A study of Homo sapiens with 6 samples.

How the data were processed

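Polyadenylated RNA of 6 cultures of the human neuroblastoma line SH-SY5Y was measured by stranded RNA sequencing. Per the labels' protocols, cells were maintained with 15% foetal bovine serum, the undifferentiated control cultures were kept at 5% serum, and the differentiated cultures went through a scheme of 9 days. Cells were collected in 3 independent experiments, libraries were made with the TruSeq Stranded mRNA kit, and inserts of 200 to 250 bp were selected. Groups and replicate numbers were taken from the sample titles, giving 3 undifferentiated and 3 differentiated libraries.

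The authors deposited a table with 23275 gene entries, each with an Ensembl identifier, a symbol and a value per library. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 and Cufflinks were used with the human genome build hg19 (GRCh37). The versions of TopHat2 and Cufflinks, the annotation release and the strand setting are not given in the sources used here. The deposited values were read as FPKM, in which fragments are normalised to transcript length and to the mapped fragments of the library: the file does not name its unit, Cufflinks gives FPKM by default, and the column sums, from 540072 to 650617, differ between libraries. Of the entries, 5828 were 0 in every library. Cufflinks can write an exact 0 for a locus whose estimate failed. MT-CO1, a gene used by every cell with mitochondria, was at 0 in all 6 libraries, so a 0 is reported here only as a listed value.

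The number of reads per library is not given in the sources used here. The spacing of low values gave ratios of depth relative to undifferentiated replicate 1 that were too uncertain to use, with a bootstrap interval of 1.04 to 1.45 for undifferentiated replicate 3. The depth behind each value is therefore unknown, and no counting interval is given. Precision is described by the spread between the 3 libraries of a group. Values of genes with near-identical copies or overlapping neighbours, among them ribosomal protein, histone, HLA and IFITM genes and IGF2, are uncertain, since the handling of shared reads is not stated.

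The values were analysed as log2(FPKM + 1) without rescaling between libraries. Genes with FPKM of at least 1 in at least 3 of the 6 libraries were tested, which left 12724 genes. Groups were compared with limma 3.58.1 in R 4.3.3, with a trend of variance on mean expression, two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A log2 fold change is on the log2(FPKM + 1) scale and understates the change of genes with low values. All adjusted p-values of genes are from this limma model. Means are given with the SD over 3 libraries. Figures were drawn with matplotlib 3.10.9.

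The test, the alternatives, the genes to be named and 32 gene lists were fixed before the data were examined. The lists cover retinoid signalling, HOX clusters, mitosis, DNA replication, adrenergic and mesenchymal neuroblastoma regulators, neuronal and synaptic genes, transmitter systems, trophic factors, ion channels, activity response genes, matrix, adhesion, guidance, Wnt and Notch genes, metabolism, stress, lysosome and cell death. They also hold ribosomal proteins, reference genes, markers of glia and of fibroblast and vascular cells, and replication-dependent histones and mitochondrially encoded genes as signs of RNA quality. Lists were tested with camera (limma), with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and adjusted over the 32 lists. The fry test (limma), which asks whether the genes of a list move on balance in a single direction, was run beside it. The rule for named genes took the 6 largest rises and 6 largest falls among called genes with a mean FPKM of at least 5 in a group and no overlap between the groups, up to 2 called members per list, and 14 genes fixed whatever their values. Some genes that the rule takes are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

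The model was tested on simulated data made from this comparison, with 200 of 12724 genes changed. Changes of 1.5-fold were recovered for 62% of the genes, 2-fold for 96% and 4-fold for 100%. Of 193 genes called in the simulation, 16 were unchanged. A shifted list was called and 0 of 20 unshifted lists were. The simulated genes varied independently of each other, whereas the estimated correlation in the data reached 0.89 (DNA replication). The simulation therefore does not show how often lists of correlated genes are called wrongly. It also held no library that lay apart from its group. Far fewer genes were changed in it than the 6378 called in the data, and the Benjamini-Hochberg cutoff depends on how many genes change. The shares recovered and wrongly called therefore hold for the simulation and were not measured for this comparison.

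Alternatives fixed in advance were pseudocounts of 0.1 and 0.01, no filter and a filter at FPKM 5, quantile, median-of-ratios and TPM scaling, limma without the trend and with library weights, the replicate number as a block, an estimated inter-gene correlation, and leaving out each library. Alternatives chosen after seeing the data were leaving out the 43 tested genes listed at 0 in any library, TPM scaling without the mitochondrially encoded genes, and removal of a spline (5 degrees of freedom each) of GC content and transcript length. GC content and length came from GENCODE 29 transcripts read with Biostrings 2.70.1, and 12483 of the tested identifiers (98.1%) had a transcript. That annotation is on another genome build than the deposited values, so it was used for these properties alone and no coordinates are given. Tests on read counts were not used, because no counts were analysed here.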

Results

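SH-SY5Y is an established human neuroblastoma line of sympathetic lineage that is widely used as a model of neurons. Gene expression was measured in 3 libraries of undifferentiated cells and 3 of cells taken through a differentiation scheme in 2 steps. The first step was 6 days with 10 µM all-trans retinoic acid, which acts through nuclear receptors, at 5% serum. The next was 3 days in neurobasal medium with 50 ng/ml of the neurotrophin BDNF, 2 mM dibutyryl-cAMP, a cell-permeable cAMP analogue, 20 mM KCl, which depolarises the membrane, and B27 supplement. The series asks how the transcriptome differs between the differentiated and undifferentiated state. Medium and supplements differ between the groups, and the days in culture of the undifferentiated cells are not given in the sources used here, so each difference below belongs to the scheme as a whole.

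Between 12266 and 12674 entries per library had FPKM of 1 or more, and the read depth is unknown. Across genes, which are not independent replicates, the undifferentiated libraries correlated at Pearson r of 0.993 to 0.996 and differentiated replicates 2 and 3 at 0.993. Differentiated replicate 1 lay apart, at 0.972 with replicate 2 and 0.967 with replicate 3. Libraries of different groups correlated at 0.862 to 0.918. No columns were identical.

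**Figure D1:**
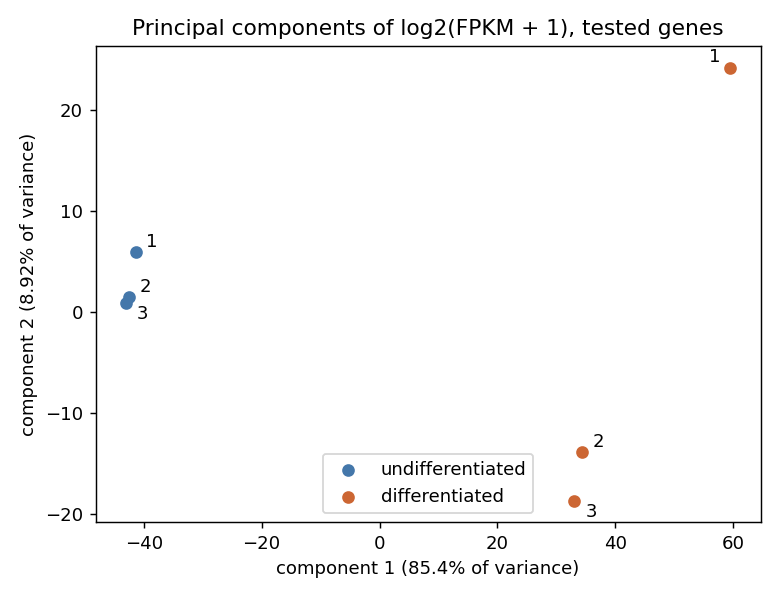
Principal components of log2(FPKM + 1) over the tested genes, with each point a library, numbered by replicate and coloured by group. Component 1 (85.4% of the variance) separates the groups, and component 2 (8.92%) separates differentiated replicate 1, at 24.3, from differentiated replicates 2 and 3, at -13.9 and -18.7.

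Expression differed at 6378 of the 12724 tested genes (50.1%; limma, adjusted p under 0.05). Of these, 2882 rose and 3496 fell in the differentiated cells, a share of 45.2% rising. Changes of at least 1 on the log2 scale numbered 876 rises and 640 falls. At 8012 tested genes (63.0%) the groups did not overlap, where chance gives 10%. The split depended on scaling: rescaled to TPM, 3913 genes rose and 1702 fell (69.7% rising), with the median of all genes moved by 0.16. With the mitochondrially encoded genes kept out of the TPM sums, 45.5% rose. Median-of-ratios scaling gave 3336 rises and 3221 falls (50.9% rising). Without differentiated replicate 1, 3242 genes rose and 3769 fell, and without undifferentiated replicate 2, 2224 rose and 2195 fell.

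Among the genes that met the naming rule, the largest rise on the log2(FPKM + 1) scale was that of NPPC (ENSG00000163273), the precursor of C-type natriuretic peptide, from 0.139 ± 0.0511 to 85.1 ± 20.3 FPKM (SD, n = 3 in each group; log2 fold change 6.22, SE 0.16, adjusted p = 3.58e-07). HGF (ENSG00000019991), the hepatocyte growth factor, rose from 0.266 ± 0.142 to 60.2 ± 5.65 FPKM (log2 5.60, SE 0.12, adjusted p = 1.68e-07). ECEL1 (ENSG00000171551), a membrane metallopeptidase of neurons, rose from 1.82 ± 0.502 to 129 ± 4.42 FPKM. The retinoic acid binding protein CRABP2 (ENSG00000143320) rose from 7.10 ± 1.22 to 364 ± 24.2 FPKM, and the membrane protein TM4SF1 (ENSG00000169908) from 0.0937 ± 0.0504 to 45.3 ± 10.9 FPKM. The complement regulator CFI (ENSG00000205403) also rose, but its differentiated values of 149.6, 39.3 and 19.0 FPKM spread widely (log2 5.59, SE 0.61, with 4.79 without replicate 1 and 6.25 without replicate 3). Among the falls, the chemokine receptor CXCR4 (ENSG00000121966) went from 27.7 ± 0.927 to 0.833 ± 0.466 FPKM (33.2-fold lower in the mean, SE of the log2 fold change 0.17, adjusted p = 5.23e-06). The transcription factor TBX3 (ENSG00000135111) fell from 91.2 ± 9.64 to 5.06 ± 0.746 FPKM (log2 -3.93, SE 0.12, adjusted p = 1.07e-06). RPH3A (ENSG00000089169), rabphilin, a Rab effector on synaptic vesicles, fell from 40.7 ± 1.60 to 2.57 ± 1.23 FPKM (log2 -3.62, SE 0.25). Ranked above these by the rule were MT-ATP8, MT-CO3 and MT-ATP6, which are listed at 0 in all 3 differentiated libraries. MT-ATP8 stood at 51418, 47706 and 50299.8 FPKM in the undifferentiated libraries.

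Genes of retinoid signalling rose. Of 18 tested members, 13 rose, 2 fell and 3 did not pass (15 and 2 adjusted over the list alone; camera adjusted p = 2.01e-05, and adjusted p = 0.542 with an estimated correlation). The retinoic acid hydroxylases CYP26B1 and CYP26A1, direct targets of the receptors, went from 0.0582 ± 0.0219 to 17.3 ± 9.57 FPKM (log2 3.99, SE 0.30) and from 0.0319 ± 0.0185 to 13.5 ± 7.51 FPKM (log2 3.69, SE 0.30, adjusted p = 8.87e-05). The receptor gene RARB rose from 3.44 ± 0.989 to 16.2 ± 4.07 FPKM. Of the HOX genes, which pattern the body axis, 14 of 39 were tested and 4 rose, 4 fell and 6 did not pass (4 and 4 adjusted over the list alone; adjusted p = 0.684), with 2 falls without undifferentiated replicate 2. HOXD10 rose from 5.81 ± 0.230 to 12.5 ± 1.11 FPKM and HOXD11 from 6.22 ± 0.673 to 13.2 ± 0.584 FPKM.

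Genes of the cell cycle fell. All 38 tested mitosis genes fell (38 adjusted over the list alone; median log2 -1.40, and -1.16 without differentiated replicate 1), with camera adjusted p = 4.61e-13, and adjusted p = 0.642 with an estimated correlation. Of 38 DNA replication genes, 37 fell (37 adjusted over the list alone; median -1.22, and -1.03 without differentiated replicate 1), with adjusted p = 4.22e-11, and adjusted p = 0.642 with an estimated correlation. The exception, named after its value was seen, was GINS4 (log2 0.10). MKI67, the proliferation marker Ki-67, fell from 34.5 ± 2.01 to 10.6 ± 4.20 FPKM (log2 -1.70, SE 0.26, adjusted p = 0.00145). CENPA, the centromeric histone H3 variant, fell from 29.1 ± 6.21 to 7.72 ± 1.83 FPKM, and the spindle checkpoint kinase BUB1B from 37.5 ± 1.24 to 11.6 ± 4.96 FPKM. RRM2, a subunit of ribonucleotide reductase, fell from 109 ± 1.65 to 26.4 ± 12.1 FPKM, with 12.4 FPKM in differentiated replicate 1 against 34.3 and 32.5 in the others. The helicase factor CDC45 fell from 30.4 ± 2.53 to 8.98 ± 2.86 FPKM. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, did not pass: it averaged 248 ± 13.8 and 315 ± 137 FPKM (log2 0.26, SE 0.26, adjusted p = 0.441), and its log2 fold change was -0.07 without differentiated replicate 1.

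Among regulators of the 2 cell states described in neuroblastoma, the mesenchymal set rose and the adrenergic set was mixed. Of 18 mesenchymal genes, 13 rose and 2 fell (13 and 2 adjusted over the list alone; camera adjusted p = 0.000167, and adjusted p = 0.642 with an estimated correlation), with 1 fall without undifferentiated replicate 2 or 3. TGFB1, the growth factor TGF-β1, rose from 7.81 ± 0.162 to 37.1 ± 18.9 FPKM and FN1, fibronectin, from 5.33 ± 0.665 to 24.3 ± 5.17 FPKM. Of 23 adrenergic genes, 6 rose, 5 fell and 12 did not pass (6 and 5 adjusted over the list alone; adjusted p = 0.684, in direction up with a median of -0.05 and a mean of 0.06). Without differentiated replicate 1, 10 rose and 7 fell and the median was 0.15, and without undifferentiated replicate 3 the median was 0.06. The transcription factor DACH1 rose from 0.788 ± 0.191 to 10.3 ± 4.96 FPKM. MYCN averaged 1.51 ± 0.491 and 1.39 ± 0.908 FPKM (log2 -0.14, SE 0.30, adjusted p = 0.724), with a log2 fold change of 0.22 without differentiated replicate 1 and 0.01 without undifferentiated replicate 3.

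Neuronal structural genes moved in both directions, and the fixed markers MAP2 and GAP43 fell. In the cytoskeleton and growth cone list, 4 of 31 genes rose, 13 fell and 14 did not pass (5 and 13 adjusted over the list alone; adjusted p = 0.134). Without differentiated replicate 1, 9 rose and 14 fell. PRPH, the intermediate filament protein peripherin, rose from 1.64 ± 0.444 to 19.7 ± 3.73 FPKM. The neuronal RNA-binding protein gene ELAVL2 fell from 27.4, 25.1 and 23.9 FPKM to 5.14 ± 0.266 FPKM (log2 -2.10). MAP2, a dendritic microtubule protein, fell from 69.4 ± 2.49 to 36.7 ± 7.46 FPKM (log2 -0.92, SE 0.14, adjusted p = 0.00157). GAP43, a growth cone protein, fell from 70.3 ± 5.44 to 38.7 ± 7.86 FPKM (log2 -0.86, SE 0.14). MAPT, which encodes tau, did not pass, at 15.1 ± 2.54 and 19.6 ± 6.70 FPKM (log2 0.31, SE 0.24, adjusted p = 0.304), but passed without differentiated replicate 1 (log2 0.58, adjusted p = 0.00516, the lowest of a range up to 0.753 over 15 alternatives). RBFOX3, which encodes the marker NeuN, was below the filter at 0.385 ± 0.332 and 0.168 ± 0.0305 FPKM. Of 25 axonal transport genes, 6 rose and 9 fell (6 and 9 adjusted over the list alone; adjusted p = 0.586): the dynein chain gene DYNC1I1 rose by 2.73 on the log2 scale and the kinesin gene KIF1A fell by 1.29.

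Synaptic lists also held more falls than rises, and neither passed as a list. Of 33 genes of the synaptic vesicle and release machinery, 9 rose, 15 fell and 9 did not pass (10 and 16 adjusted over the list alone; adjusted p = 0.608), with 5 rises without undifferentiated replicate 1. The complexin gene CPLX2 fell from 41.6 ± 5.31 to 7.66 ± 2.34 FPKM and the active zone gene RIMS1 from 11.6 ± 0.981 to 2.09 ± 0.663 FPKM. Of 27 postsynaptic genes, 7 rose and 13 fell (7 and 14 adjusted over the list alone; adjusted p = 0.358). GRIN1, the obligate NMDA receptor subunit, fell from 11.3 ± 0.290 to 1.85 ± 0.661 FPKM. Of 28 voltage-gated channel genes, 8 rose and 9 fell (8 and 9 adjusted over the list alone; adjusted p = 0.727), with rises of 1.94 for the calcium channel gene CACNB2 and 1.71 for the potassium channel gene KCNQ5 on the log2 scale.

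Cholinergic genes rose. Of 12 tested, 9 rose, 1 fell and 2 did not pass (9 and 1 adjusted over the list alone; camera adjusted p = 0.00174, and adjusted p = 0.45 with an estimated correlation). The muscarinic receptor gene CHRM2 rose from 0.751 ± 0.126 to 22.9 ± 6.34 FPKM (log2 3.74, SE 0.18) and BCHE, butyrylcholinesterase, from 1.54 ± 0.378 to 11.4 ± 0.568 FPKM. CHAT, which makes acetylcholine, was below the filter at 0.0628 ± 0.0278 and 0.415 ± 0.124 FPKM. Of 18 catecholaminergic genes, 7 rose, 4 fell and 7 did not pass (7 and 5 adjusted over the list alone; adjusted p = 0.582, in direction up with a median of -0.34). Without differentiated replicate 1, 8 rose and 7 fell and the median was 0.16, and 8 fell without differentiated replicate 3 and 2 without undifferentiated replicate 1 or 2. The noradrenaline transporter gene SLC6A2 fell from 345 ± 17.0 to 66.5 ± 42.9 FPKM, with differentiated values of 17.8, 83.0 and 98.7 (log2 -2.68, and -1.92 without differentiated replicate 1). The adrenergic receptor gene ADRA2A rose from 0.371 ± 0.0650 to 5.37 ± 1.17 FPKM. TH, tyrosine hydroxylase, was below the filter at 0.139 ± 0.0251 and 0.370 ± 0.168 FPKM.

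NTRK2, which encodes the BDNF receptor TrkB, rose from 0.688 ± 0.0650 to 39.8 ± 15.9 FPKM (log2 4.52, SE 0.24, adjusted p = 1.40e-05). Of 19 genes of trophic factors and their receptors, 8 rose and 3 fell (8 and 3 adjusted over the list alone; adjusted p = 0.113, and 0.0434 without differentiated replicate 1, in a range of 0.0434 to 0.642 over 15 alternatives), with 1 fall without undifferentiated replicate 2. IGF2 rose from 44.8 ± 7.93 to 275 ± 167 FPKM, with differentiated values of 96.8, 302.6 and 427 (log2 2.36, and 2.99 without differentiated replicate 1). Of 27 genes that respond to activity or cAMP, 6 rose, 11 fell and 10 did not pass (7 and 12 adjusted over the list alone; adjusted p = 0.332). The orphan nuclear receptor NR4A3 rose from 0.142 ± 0.0234 to 8.73 ± 3.24 FPKM and the phosphodiesterase PDE10A from 5.57 ± 0.205 to 33.6 ± 5.46 FPKM.

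**Figure D2:**
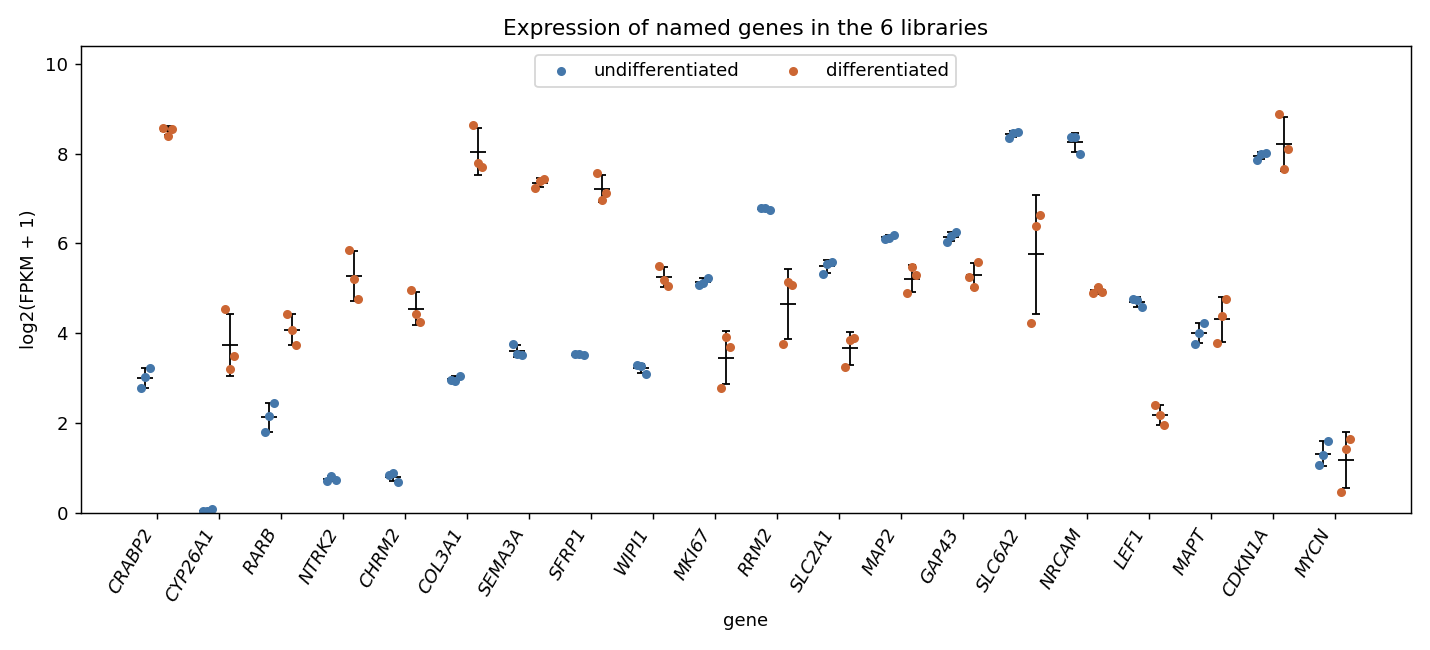
Expression of 20 named genes as log2(FPKM + 1), with each point a library, black bars the mean and SD of a group (n = 3), and colour the group. CRABP2, CYP26A1 and NTRK2 rose, MKI67, MAP2 and NRCAM fell, and MAPT, CDKN1A and MYCN did not pass the test.

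Matrix genes rose. Of 35 tested, 21 rose, 6 fell and 8 did not pass (21 and 6 adjusted over the list alone; camera adjusted p = 7.99e-06, and adjusted p = 0.642 with an estimated correlation). COL3A1, a fibrillar collagen chain, rose from 6.89 ± 0.313 to 276 ± 108 FPKM, with differentiated values of 400.4, 220.1 and 207 (log2 5.07, SE 0.23, adjusted p = 6.87e-06) and the proteoglycan gene DCN from 0.788 ± 0.393 to 22.0 ± 4.46 FPKM. Markers of fibroblast and vascular cells moved with them: 9 of 10 tested rose (9 adjusted over the list alone; adjusted p = 1.51e-06, and 0.45 with an estimated correlation). That list shares 5 genes with the matrix list, and 8 of its 15 genes had a mean FPKM of 1 or more in undifferentiated cells. Of the 31 tested matrix genes outside it, 17 rose and 6 fell. The collagen genes COL1A2 and COL6A3, abundant in fibroblasts and singled out after their values were seen, averaged 0.267 ± 0.108 and 0.252 ± 0.139 FPKM in differentiated cells, and POSTN is listed at 0 in all 6 libraries. Of 5 markers of Schwann cells and glia, 3 rose and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.0757), among them S100B, from 5.90 ± 0.836 to 10.9 ± 3.15 FPKM, and CNP, from 32.4 ± 2.57 to 55.5 ± 7.51 FPKM.

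Adhesion and guidance genes moved both ways. Of 29 integrins and adhesion molecules, 13 rose and 6 fell (13 and 6 adjusted over the list alone; adjusted p = 0.318), with 8 rises without undifferentiated replicate 3. The adhesion molecule gene NRCAM fell from 306 ± 44.5 to 30.0 ± 1.66 FPKM (log2 -3.30, SE 0.12), while NCAM2 rose from 3.00 ± 0.544 to 27.5 ± 4.54 FPKM. Of 45 axon guidance genes, 19 rose, 9 fell and 17 did not pass (19 and 10 adjusted over the list alone; adjusted p = 0.0757, and 0.0456 without differentiated replicate 1, in a range of 0.0456 to 0.642 over 15 alternatives). The secreted semaphorin SEMA3A rose from 11.2 ± 1.16 to 163 ± 11.7 FPKM (log2 3.75, SE 0.10) and SEMA3D from 0.293 ± 0.0592 to 8.27 ± 3.39 FPKM. Of 36 Wnt genes, 15 rose and 7 fell (17 and 9 adjusted over the list alone; adjusted p = 0.0757), with 4 falls without undifferentiated replicate 2 or 3. SFRP1, a secreted Wnt antagonist, rose from 10.5 ± 0.142 to 151 ± 33.7 FPKM, and LEF1, a transcription factor of the pathway, fell from 25.0 ± 1.83 to 3.55 ± 0.676 FPKM. Of 21 Notch genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone; adjusted p = 0.134). The ligand gene DLL3 rose from 4.99 ± 0.994 to 20.7 ± 1.81 FPKM. DLK1, a non-canonical ligand, rose from 103 ± 10.7 to 485 ± 338 FPKM, with differentiated values of 160.2, 460.3 and 834 (log2 1.94, SE 0.50, and 2.59 without differentiated replicate 1; adjusted p = 0.014, and 0.0583 without undifferentiated replicate 1, in a range of 7.98e-07 to 0.0583 over 15 alternatives).

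Sterol genes rose and glycolytic genes fell. Of 31 genes of sterol biosynthesis and uptake, 24 rose, 0 fell and 7 did not pass (25 and 0 adjusted over the list alone; camera adjusted p = 2.24e-09, and adjusted p = 0.45 with an estimated correlation). TM7SF2, a sterol reductase, rose from 31.6 ± 3.99 to 142 ± 55.7 FPKM. Of 25 genes of glycolysis and the hypoxia response, 18 fell, 1 rose and 6 did not pass (20 and 1 adjusted over the list alone; camera adjusted p = 0.000247, and adjusted p = 0.642 with an estimated correlation), with 3 rises without differentiated replicate 1. SLC2A1, the glucose transporter GLUT1, fell from 44.0 ± 4.46 to 11.9 ± 3.04 FPKM and PDK1, pyruvate dehydrogenase kinase, from 17.0 ± 1.09 to 5.80 ± 2.64 FPKM. Of 46 nuclear genes of oxidative phosphorylation, 6 rose and 12 fell (4 and 9 adjusted over the list alone; adjusted p = 0.721), with log2 changes no larger than the 0.59 of ATP5H and the -0.57 of NDUFV1 among those called. Rises numbered 3 without undifferentiated replicate 1 or 2, and falls 3 without undifferentiated replicate 2 or 3 and 7 without differentiated replicate 2.

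Lists of lysosomal and of stress response genes passed in the upward direction, with many members that did not pass. Of 36 genes of lysosome and autophagy, 19 rose, 2 fell and 15 did not pass (21 and 2 adjusted over the list alone; camera adjusted p = 0.000191, and adjusted p = 0.734 with an estimated correlation), with 12 rises without undifferentiated replicate 1 or 2. The median log2 fold change was 0.67. Without differentiated replicate 1 it was 0.41, with 22 rises and 3 falls. WIPI1, an autophagosome protein, rose from 8.32 ± 0.639 to 37.2 ± 5.98 FPKM. NPC2, a cholesterol carrier of the lysosome, rose from 38.7 ± 1.39 to 246 ± 190 FPKM, with differentiated values of 464, 161 and 114 (log2 2.37, and 1.78 without differentiated replicate 1). Of 27 genes of the unfolded protein and amino acid stress response, 13 rose, 4 fell and 10 did not pass (15 and 6 adjusted over the list alone; camera adjusted p = 0.00482, and adjusted p = 0.642 with an estimated correlation), with 2 falls without undifferentiated replicate 2 or 3. The endoplasmic reticulum gene CRELD2 rose from 24.4 ± 2.22 to 61.1 ± 10.7 FPKM, and SHMT2, an enzyme of serine metabolism, fell from 75.1 ± 3.41 to 29.2 ± 6.17 FPKM. Of 32 cell death genes and p53 targets, 6 rose and 10 fell (6 and 10 adjusted over the list alone; adjusted p = 0.998, in direction up with a median of 0.05, a mean of -0.05 and a median of -0.05 without differentiated replicate 1). BCL2, an inhibitor of apoptosis, fell from 10.1 ± 0.438 to 5.00 ± 2.15 FPKM (log2 -0.94, SE 0.22, adjusted p = 0.00903), and BIRC3 from 8.57 ± 1.06 to 1.53 ± 0.0969 FPKM. HRK, which promotes apoptosis, rose from 0.117 ± 0.0401 to 1.82 ± 0.395 FPKM.

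Of 61 cytoplasmic ribosomal protein genes, 13 fell, 0 rose and 48 did not pass (6 and 0 adjusted over the list alone; adjusted p = 0.318), with RPS7 at 1231 ± 73.3 and 726 ± 42.8 FPKM and RPLP0 at 1033 ± 68.0 and 640 ± 77.6 FPKM. Falls numbered 8, 6 and 5 without undifferentiated replicates 1, 2 and 3 and 8 without differentiated replicate 2. The list pointed up when values were rescaled to TPM (adjusted p = 0.498, in a range of 0.0653 to 0.892 over 15 alternatives). Of 14 reference genes, 2 rose and 7 fell (2 and 7 adjusted over the list alone; adjusted p = 0.272), with 1 rise when undifferentiated replicate 1, 2 or 3 was left out and 4 falls without undifferentiated replicate 2 or 3. B2M, the light chain of HLA class I, rose from 371 ± 2.31 to 968 ± 657 FPKM (log2 1.18, SE 0.38, adjusted p = 0.0338), with differentiated values of 1722, 667 and 514; the adjusted p was 0.0907 to 0.0961 when an undifferentiated library was left out, in a range of 0.000208 to 0.0961 over 15 alternatives. Of 13 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 6 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.267), led by HIST2H2BE (log2 1.20) and HIST1H2AE (log2 0.86). Rises numbered 3 without undifferentiated replicate 2, and falls 1 and 0 without undifferentiated replicates 1 and 3. Of 12 mitochondrially encoded genes, 3 are listed at 0 in every differentiated library, 1 rose and 8 did not pass (3 lower and 1 higher adjusted over the list alone; adjusted p = 0.096, and 0.00685 without differentiated replicate 1 and 0.0409 without undifferentiated replicate 2, in a range of 0.00685 to 0.757 over 15 alternatives). Without differentiated replicate 1, 5 were lower, and without differentiated replicate 3, 2 rose. Mitochondrially encoded genes made up 23.4% to 26.7% of the FPKM sum in undifferentiated libraries and 11.6% to 17.1% in differentiated libraries. With the genes listed at 0 kept out of both sums, the shares overlapped, at 12.4% to 14.9% and 11.6% to 17.1%.

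In all, 11 of the 32 lists passed with camera at the preset correlation, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. With fry, 17 lists passed, 10 of them among those 11. Unlike camera, fry does not compare a list with the other genes, of which many changed (50.1% of tested genes were called). Its mixed form, which asks for change in either direction, passed 32 lists, so it did not tell the lists apart. For lysosome and autophagy the fry adjusted p was 0.0651.

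**Figure D3:**
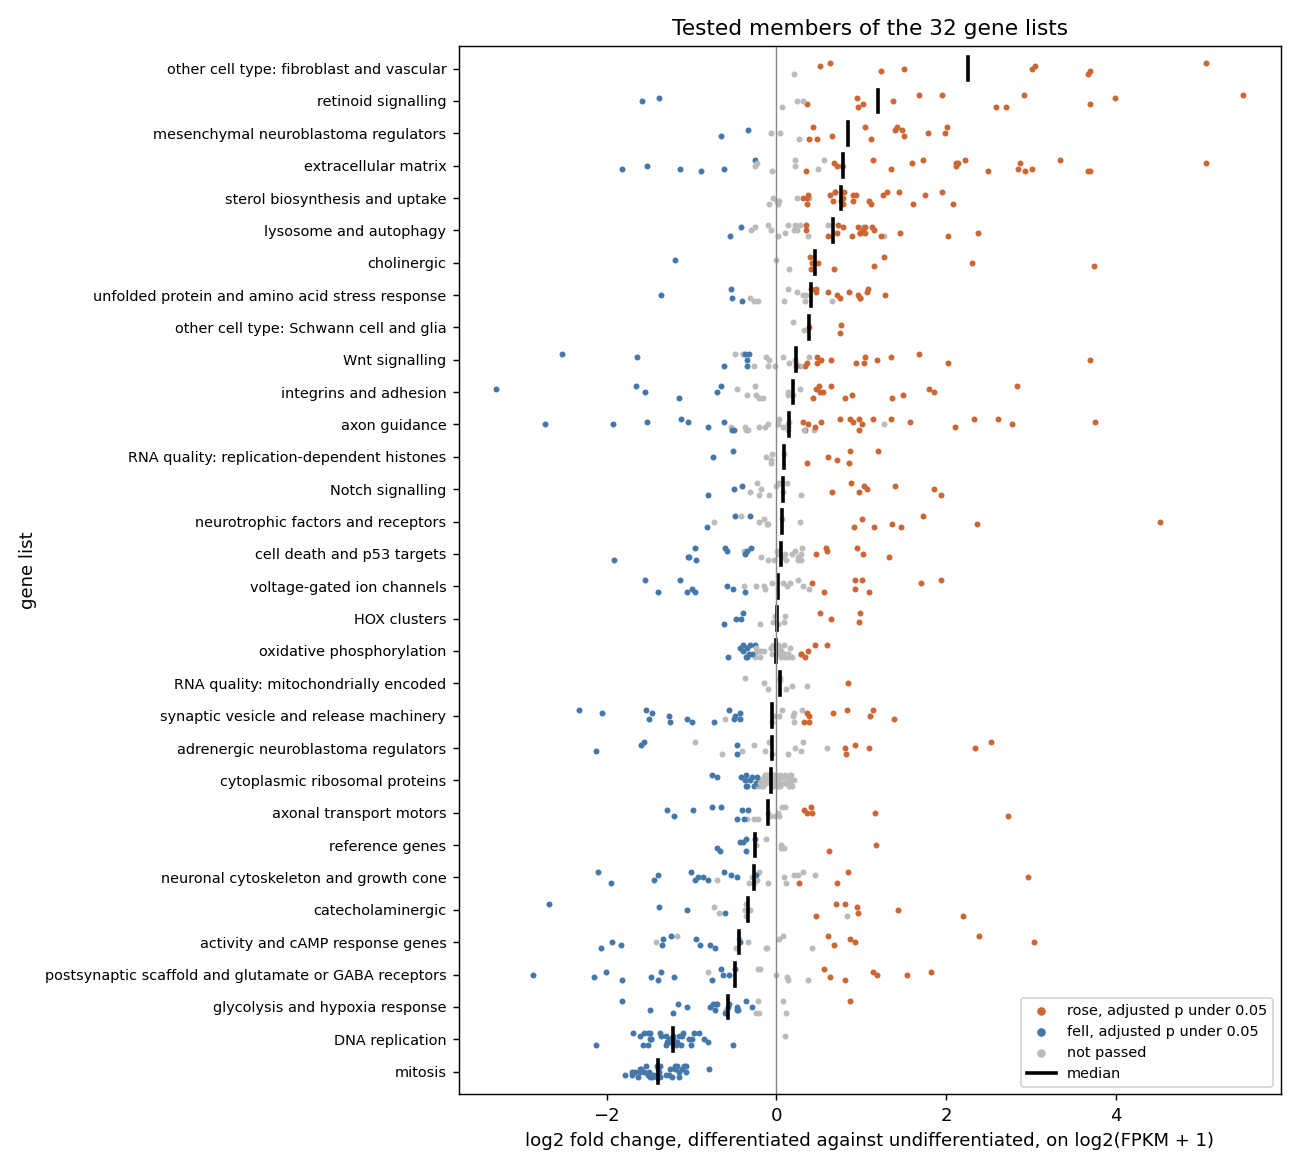
Log2 fold changes of the tested members of the 32 gene lists, with each point a gene, colour marking genes that rose, fell or did not pass, and black bars the median. The 3 mitochondrially encoded genes listed at 0 in the differentiated libraries are left out. Mitosis (median -1.40) and DNA replication (-1.22) lie lowest, and the fibroblast and vascular markers (2.26) and retinoid signalling (1.20) highest.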

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

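The test of GC content and transcript length was set before its result was seen; the tests of depth and of a shared response were chosen after the data were seen. Among genes too low for the comparison, 142 reached FPKM of 1 in differentiated replicate 1 and in no other library, against 36 for differentiated replicate 2 and 41 for replicate 3. They were singled out because they lie outside the comparison and above the level of the undifferentiated libraries. In all, 358 untested genes reached that level in 1 or 2 differentiated libraries and no undifferentiated library, and 120 the other way round. The highest were C5orf46 (5.20 FPKM in differentiated replicate 1, against 0.537 and 0.455 in the other differentiated libraries) and TFPI, an inhibitor of coagulation (4.09 FPKM in differentiated replicate 1 and 0.634 in replicate 2). ANXA1, annexin A1, is listed at 0 in the undifferentiated libraries and stood at 2.61, 0.489 and 0.157 FPKM in the differentiated libraries.

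These genes belong to a wider pattern: differentiated replicate 1 lay apart, with 193 tested genes more than 1 higher on the log2 scale than in both other differentiated libraries and 93 more than 1 lower. A lower read depth as the cause is argued against by the 3181 most abundant tested genes, where the spread of replicate 1 against replicate 2 was 2.87 times that of replicate 2 against replicate 3 (SD of 0.401 and 0.14). GC content and transcript length accounted for 5.34% of the variance of its deviation. A proportionally larger copy of the other libraries' response accounted for 13.3% of replicate 1's excess variance over replicate 2 (15% with replicates 2 and 3 exchanged). Such a copy is therefore not the whole cause, although the deviation correlated across genes with that response (r = 0.322 and 0.349). A further advanced state that changes other genes is not covered by this test and stays open. A difference between the independent experiments, in the cultures or in their handling, stays open and was not tested.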

How the results depend on the processing

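Leaving out genes listed at 0, TPM without mitochondrially encoded genes and the GC and length spline were chosen after seeing the data. The number of called genes was 5341 to 8344 over the alternatives that used all libraries and 4419 to 7011 when a library was left out. The 5341 came with the filter at FPKM 5, where 10330 genes were tested. With the same 12724 genes and all libraries, the lowest was 5615, after TPM scaling. Where still tested, 0 of the 1516 large changes reversed in any alternative. Changes of that size could hardly reverse under rescaling, so the 0 says little for those alternatives. Genes that fell numbered 1702 after TPM scaling and 2195 to 3769 when a library was left out, lowest without undifferentiated replicate 2. TPM without the mitochondrially encoded genes gave 3507, so the mitochondrially encoded genes in the sums account for the TPM split. Those other than the genes listed at 0 had overlapping sums, of 69503 to 80434 FPKM in undifferentiated and 63040 to 103578 in differentiated libraries. The groups' sums therefore differ through MT-ATP8, MT-CO3 and MT-ATP6, listed at 0 in every differentiated library. The 11 list calls became 0 with an estimated correlation and were 11 to 14 when a library was left out. Of 1152 alternative values of named genes, 1144 kept their direction and side of the threshold, 4 lost the call (DLK1 once, B2M 3 times), 1 gained it (MAPT) and 3 reversed, all of them of genes that were not called: the log2 fold change ranged from -0.37 to 0.22 for MYCN and from -0.073 to 0.53 for CDKN1A when a library was left out. Of 480 values of lists, 450 kept both, 11 lost the call, all with the estimated correlation, 4 gained it and 15 reversed, none of a called list. Reversed lists had adjusted p of 0.924 for voltage-gated channels, 0.53 for oxidative phosphorylation, 0.923 for cell death and 0.498 for ribosomal proteins after TPM scaling, and of 0.768 for voltage-gated channels and 0.416 for mitochondrially encoded genes after quantile normalization. The cell death list reversed with p of 1 at pseudocount 0.1, 1 without genes listed at 0, 0.969 with TPM without mitochondrially encoded genes, 0.972 with the spline and 0.55 to 0.946 without a library; HOX genes reversed with 0.972 under the spline and mitochondrially encoded genes with 0.651 without genes listed at 0. Except for the TPM split, the cause was not tested. Pairing by replicate number rests on the number alone: deviations from the group means correlated at 0.152, 0.091 and 0.14 for numbers 1 to 3, each the best match of its library, a hint from the data and not from the design. With the replicate block, 6406 genes were called, 6083 of them shared with the unblocked model, and 11 lists. The 10 splits of the 6 libraries are too few for a share under 0.1 (1 split, the real one, reached its 6378 genes; highest other 0, limma, with 170 at an unadjusted p under 0.05). Since the read depth is unknown, differences at genes of low FPKM are limited to an extent that could not be measured.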

Other observations

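The 3 gene lists and the tests of this part, other than leaving out a library, were chosen after the data were seen. Several chemokine and NF-κB target genes fell, CCL2 among them. A list of NF-κB targets was drawn up after the values were seen. Of its 21 tested members other than CCL7 and IL8, 17 fell, 1 rose and 3 did not pass, with a median log2 fold change of -0.83. CCL2, a monocyte chemokine, fell from 519 ± 47.8 to 49.2 ± 29.3 FPKM (log2 -3.56), CXCL10 from 5.76 ± 0.588 to 0.265 ± 0.128 FPKM and UBD from 9.95 ± 0.801 to 0.138 ± 0.179 FPKM, with differentiated values of 0.340, 0 and 0.0733. Outside these counts, CCL7, IL8 and IL1B are listed at 0 in all differentiated libraries, with 8.46 to 12.0, 6.48 to 7.95 and 2.85 to 4.03 FPKM in undifferentiated libraries. The feedback inhibitors NFKBIA (log2 -1.11) and TNFAIP3 (-1.26) fell, whereas VCAM1 rose (1.33). That NF-κB target genes as a class fell together is a hypothesis that these data leave open: the list was made of genes whose values had been seen, so its test decides nothing (camera, adjusted over 3 lists, p = 8.36e-08 with CCL7 and IL8 and 1.84e-06 without them, and adjusted p = 0.192 without them with an estimated correlation). When each library was left out in turn, 16 to 18 fell and 1 rose.

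Of 24 tested interferon-stimulated and antigen presentation genes, 17 rose, 1 fell and 6 did not pass (13 to 19 rose and 1 to 3 fell when each library was left out in turn, the most of both without differentiated replicate 1; camera adjusted p = 5.03e-06, and adjusted p = 0.241 with an estimated correlation). IFITM2 rose from 3.17 ± 0.226 to 66.3 ± 24.8 FPKM, with differentiated values of 93.8, 59.6 and 45.5. HLA-E rose from 2.90 ± 0.475 to 24.1 ± 10.5 FPKM and BST2 from 0.918 ± 0.436 to 12.4 ± 4.46 FPKM. MX1, a common interferon target, was below the filter at 0.124 ± 0.0858 and 0.094 ± 0.0747 FPKM. Of 14 ID genes and BMP feedback genes, 9 fell, 1 rose and 4 did not pass (8 to 10 fell and 1 to 2 rose when each library was left out in turn, with 10 and 2 without differentiated replicate 1; camera adjusted p = 0.00254, and adjusted p = 0.192 with an estimated correlation). ID2, an inhibitor of proneural basic helix-loop-helix factors, fell from 136 ± 8.84 to 15.6 ± 5.83 FPKM, and ID1 from 64.7 ± 6.99 to 10.3 ± 7.22 FPKM, with differentiated values of 18.5, 7.14 and 5.17. BMP7 rose (log2 1.55). These lists too were chosen after their members' values were seen, so each joint movement is a hypothesis that the tests do not decide, and none was tied to a single component of the scheme.

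The rise of fibroblast markers and matrix genes raises the question of other cells in the differentiated cultures. Fibroblasts would bring their abundant transcripts together. The highest differentiated mean among COL1A2, COL6A3 and POSTN was 0.267 FPKM, 0.0967% of that of COL3A1 (276 FPKM). These 3 genes were singled out after their low values were seen, and 9 of the 10 tested fibroblast and vascular markers fixed in advance rose. COL1A2 went from 0.929 ± 0.299 to 0.267 ± 0.108 FPKM, and COL6A3 from 0.0418 ± 0.0211 to 0.252 ± 0.139 FPKM. POSTN is listed at 0 in both groups, and a listed 0 can be a failed estimate. Since the 3 genes were chosen after these values were seen, they do not decide whether fibroblasts were present. Other cells are not excluded either. Of the 26 genes of both lists that rose, 25 still rose after the GC and length spline, so these properties do not account for the pattern. All 26 still rose without differentiated replicate 1, but genes high in that library alone could hardly have been called. Over all tested members without it, 24 of 35 matrix genes rose and 8 fell, and 9 of 10 fibroblast and vascular markers rose. That library alone therefore does not account for the pattern. A candidate explanation is a change of state in the SH-SY5Y cells under the scheme. RNA of whole cultures cannot tell it apart from a change in the mix of cells, and neither hypothesis was tested here.

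MT-ATP8, MT-CO3 and MT-ATP6 are listed at 0 in the differentiated libraries. Among the other 9 tested mitochondrially encoded genes, 1 rose and 0 fell, with a median log2 fold change of 0.039 (range -0.37 to 0.84). The SE of that median, 0.14, is over genes, which are not independent replicates. Without differentiated replicate 1, 5 of the 12 tested genes were lower, those listed at 0 included. A fall of all mitochondrially encoded RNA as large as that listed for MT-ATP8, MT-CO3 and MT-ATP6 is argued against. A smaller fall is not excluded. A failed estimate at these loci in the authors' quantification is a candidate explanation: MT-CO1 is listed at 0 in all 6 libraries, the 3 undifferentiated ones included. Without the genes listed at 0, the mitochondrial share of the FPKM sum was 12.4% to 14.9% in undifferentiated and 11.6% to 17.1% in differentiated libraries, so the lower share of the differentiated libraries does not hold without them.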
